A study of Mus musculus with 6 samples.

How the data were processed

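The data were 6 bulk RNA-seq libraries of CD8 T cells from male C57Bl6 mice, 3 electroporated with Ar-directed and 3 with non-targeting guide RNAs, enriched with magnetic beads after 72 h of CD3 and CD28 stimulation. Groups and replicate numbers were taken from the sample titles. The deposited table gives one TPM value per gene symbol and library, for 55228 symbols. The TPM values were made by the authors with RSEM 1.3.1 on mm10 or GRCm38, per the submitters' processing notes, which name both build names. The aligner, the annotation release, the strandedness of the libraries and any filter on reads are not given in the sources used here. TPM divides each gene's estimated reads by its effective length and scales every library to the same sum, so a change in a few abundant genes shifts all others, and multi-mapping reads are shared out among similar genes by the model. TPM keeps no depth, so the depth per library is unknown, and no counting error could be given. The precision of each value is therefore given as the spread between libraries.

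Values were transformed to log2(TPM + 1), and a difference on this scale understates the change of genes near or below 1 TPM. The 11569 genes with a mean TPM of at least 1 over the 6 libraries were tested, which held at least 99.8% of the TPM of each library. The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, without covariates, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Differences are AR-deficient minus control. For Ar the group difference was also tested with an exact two-sided permutation test over the 20 assignments of labels. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over the 31 lists with at least 5 tested genes, out of 33 lists. The lists cover T cell functions, signalling, steroid response, metabolism, stress, proliferation, RNA quality and markers of other cell types. The camera test allowed a mean-variance trend. That setting was not part of the fixed design and was chosen after a first look at the list results without it. A camera test with an estimated correlation, and fry, which tests whether the genes of a list move one way on balance, were run as alternatives. Counts adjusted over the list alone use Benjamini-Hochberg within one list. The tests, lists, gene panel, alternatives and the rule for named genes were fixed before the data were examined, apart from the exceptions named here and in the closing section.

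Genes were named by a rule with 5 parts: the targeted gene, the 10 genes per direction with the largest difference among those past the threshold whose groups do not overlap, filled to 10 by the lowest unadjusted p where fewer passed, a panel of 22 genes, up to 4 members with the lowest p of each list past the threshold and of the cytokine, cytotoxicity, androgen and p53 lists, and the 2 members of highest TPM of each marker or quality list. Since no gene passed, the second part was filled by the lowest p throughout. Predicted genes, antigen receptor segments and pseudogenes were counted but not named. The few further genes named were chosen after their values were seen: Stat1, Tcrg-C2, Trgv2, Trdc and Ighd in the report, and those in the closing section. Positions, gene types, transcript lengths, GC content and overlaps came from GENCODE M21 on GRCm38, in which 11471 of the tested symbols (99.1%) were found. Reads of overlapping genes could be exchanged, on opposite strands too since the strandedness is not known. Besides the overlaps given in the report, Aldoa overlaps Fam57b, Tpi1 Spsb2, Gapdh Iffo1, Pdia3 Catsper2, Il2 Adad1, Herc3 Nap1l5 and mt-Nd5 mt-Nd6 on the opposite strand, and Cox17 overlaps Gm21987, mt-Nd4l mt-Nd4 and mt-Atp8 mt-Atp6 on the same strand. Some other named genes overlap predicted genes, pseudogenes or noncoding RNAs, which are not listed.

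The scripts were tested on simulated data with the 11569 genes and 6 libraries, in 5 runs with 200 changed genes. The test found 50.1% of genes changed by 0.25, 85.7% of those changed by 0.5 and 95.8% of those changed by 1 on the log2 scale, and 4.02% of its calls were false. A list shifted by 0.2 was called in 5 of 5 runs and no other list was called, but simulated genes varied independently, which real genes of a pathway do not. The highest share of identical nonzero values between libraries was 0.951%, so no library was a copy of another.

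The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a minimum mean of 5 TPM, median-of-ratios scaling, quantile normalization, rescaling without mitochondrially encoded and ribosomal protein genes, no mean-variance trend, robust eBayes, array weights, the replicate number as a block, a threshold of 0.1, leaving out each library in turn, and, chosen after seeing the data, a correction for transcript length and GC content. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.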

Results

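Bulk RNA-seq profiles were obtained from 6 libraries of mouse CD8 T cells, the cytotoxic lymphocytes of the adaptive immune system, from male mice of the C57Bl6 strain. The cells were electroporated either with guide RNAs directed at Ar, the gene of the androgen receptor, or with non-targeting guide RNAs, and were magnetically enriched after 72 h of stimulation through CD3 and CD28. There were 3 libraries labelled AR-deficient and 3 control libraries. Expression was given as TPM, the abundance of a gene's transcripts scaled to the same total in every library, a unit that keeps no read depth, so the depth of each library is unknown. Between 11466 and 11561 genes per library reached a TPM of 1 or more. Pairwise correlations of log2(TPM + 1) across genes lay between 0.991 and 0.994, and the median coefficient of variation at a mean TPM of 10 or more was 3.11% within the AR-deficient and 3.06% within the control group. The labels do not say that the libraries came from separate animals or cultures, so the p-values measure the spread between these libraries, which may be technical. The comparison asked how the transcriptome of activated CD8 T cells differs when the androgen receptor gene is targeted.

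The targeted gene, Ar, was lower in each AR-deficient library than in any control library. Ar (ENSMUSG00000046532.8) lies on the plus strand of chromosome X from 98148769 to 98323215 in GRCm38. Its level was 0.92, 0.77 and 0.61 TPM in AR-deficient libraries 1, 2 and 3, and 1.40, 1.24 and 1.23 TPM in control libraries 1, 2 and 3. The means were 0.767 ± 0.155 TPM and 1.29 ± 0.0954 TPM (SD, n = 3 each), so the AR-deficient mean was 59.4% of the control mean. The log2(TPM + 1) difference was -0.38 with an SE of 0.096. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow, and limma gave an adjusted p of 0.152 over all genes. Because Ar lies near 1 TPM, the size of the log2 difference depended on the pseudocount, and was -0.70 with a pseudocount of 0.1 and -0.13 with one of 5. Insertions and deletions left by editing need not lower an mRNA, so this level checks the labels only in part.

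At the level of single genes, the profiles of AR-deficient and control cells differed by small amounts, and no gene passed the threshold over all genes. The lowest p-values belonged to Drc1, an axonemal dynein regulatory protein, and Ptms, which encodes parathymosin. Drc1 (chromosome 5, 30281388 to 30366695, plus strand) had 14.2 ± 0.915 TPM in AR-deficient and 8.36 ± 0.546 TPM in control cells (SD, n = 3 each). Ptms (chromosome 6, 124913681 to 124920103, minus strand) had 80.3 ± 1.96 TPM against 98.3 ± 0.299 TPM. Both had a limma adjusted p of 0.0629. Drc1 overlaps the predicted gene Gm43755 on the same strand, and Ptms overlaps A230083G16Rik on the opposite strand. Other genes with higher AR-deficient values were Nqo1, a quinone reductase, at 7.36 ± 0.320 against 5.09 ± 0.318 TPM, Il18rap, a subunit of the interleukin 18 receptor, at 17.9 ± 0.732 against 14.4 ± 0.345 TPM, and the proliferation marker Mki67 at 130.8 ± 4.44 against 111.6 ± 0.974 TPM. Sgk3, Fut8, Gvin1, Entpd5, Ccdc191 and the interferon-inducible GTPase gene Igtp completed the 10 named genes of lowest p with higher values, with TPM ratios from 1.16 for Igtp to 1.58 for Ccdc191. Among genes with lower values, Ramp3, a receptor activity-modifying protein, had 5.81 ± 0.552 against 9.63 ± 0.920 TPM, and the protease inhibitor gene Cst3 had 60.0 ± 0.743 against 71.3 ± 1.58 TPM. Dmwd, Crabp2, Cox17, Avpi1, Gapdh, Mif and Uqcrq completed the 10 named genes with lower values, with TPM ratios from 0.773 for Dmwd to 0.888 for Gapdh. Ccdc191 overlaps Qtrt2 on the opposite strand, Igtp overlaps Irgm2 on the same strand, and pseudogenes resemble Gapdh, so part of their signal could not be assigned.

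With limma, 0 of 11569 tested genes were higher and 0 were lower at an adjusted p under 0.05, while 1795 genes, 15.5%, had an unadjusted p under 0.05 where 578 were expected by chance. Of these, 986 were higher and 809 lower in AR-deficient cells, and their median absolute log2 difference was 0.14. Median-of-ratios scaling gave 900 higher and 1059 lower at the same unadjusted threshold, so neither direction predominated under both scalings. Without control library 1 there were 678 higher and 1055 lower, and without control library 2 there were 651 higher and 527 lower, 1178 in all. The 3 values of a group lay entirely above those of the other in 21.8% of genes, where chance gives 10%. At an adjusted p under 0.1, 47 genes were higher and 61 lower, 108 in all, a count that one library could end. It was 0 without AR-deficient library 3, 2 without AR-deficient library 2, 6, 10 and 14 without control libraries 2, 1 and 3, and 105 without AR-deficient library 1. Array weights, which let libraries differ in reliability, called 1094 higher and 1095 lower. Leaving out AR-deficient library 1 called 11 higher and 7 lower, leaving out control library 2 called 3 higher and 2 lower, leaving out AR-deficient library 2 or control library 3 called 1 higher and 0 lower, leaving out control library 1 called 0 higher and 2 lower, and leaving out AR-deficient library 3 called none.

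**Figure D1:**
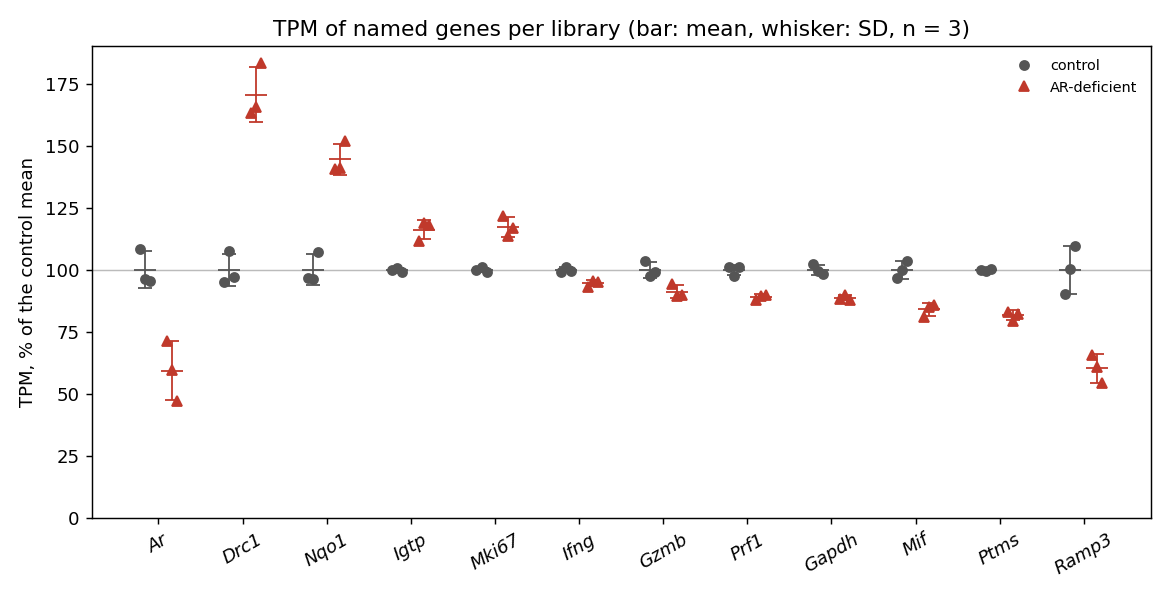
TPM of 12 named genes in each library, as a percent of the gene's control mean (vertical axis, from 0), for control (grey circles) and AR-deficient libraries (red triangles). Horizontal bars are group means and whiskers the SD of 3 libraries. The Ar mean in AR-deficient cells is at 59.4%, Drc1 and Nqo1 lie highest, and the Gzmb difference, lower here, is 0 after quantile normalization because Gzmb has the same rank in every library.

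Genes of glucose use, of the hypoxia response and of the amino acid response driven by ATF4 were lower in AR-deficient cells as groups. Of the 33 tested genes of the ATF4 list, 33 had a negative difference and 11 were lower when adjusted over the list alone, against 0 over all genes. They included Slc7a5, an amino acid transporter, at 220.3 ± 2.37 against 236.8 ± 2.90 TPM, the arginine transporter gene Slc7a3 at 11.9 ± 0.659 against 14.5 ± 0.380 TPM, and Atf3 at 37.0 ± 2.08 against 43.2 ± 1.66 TPM (SD, n = 3 each). Of the 26 glycolysis genes, 23 had a negative difference and 13 were lower when adjusted over the list alone, against 0 over all genes. The lactate exporter gene Slc16a3 had 64.7 ± 5.90 against 87.9 ± 2.27 TPM, and the glycolytic enzyme genes Gapdh, Aldoa and Tpi1 had 0.888, 0.911 and 0.881 times their control means. In the hypoxia list, 17 of 20 genes had a negative difference and 8 were lower when adjusted over the list alone, against 0 over all genes. Vegfa, which encodes an angiogenic factor, had 15.6 ± 1.12 against 19.1 ± 1.15 TPM, and Ddit4, a stress-induced inhibitor of mTOR signalling that also belongs to the ATF4 list, had 33.0 ± 2.98 against 41.7 ± 1.92 TPM. The mean log2 differences were -0.11 for the ATF4 list, -0.11 for glycolysis and -0.15 for hypoxia, and the adjusted p from camera with its preset correlation was 1.98e-11, 9.57e-11 and 4.75e-07. With an estimated correlation no list passed, and the adjusted p was 0.501 for the ATF4 list, 0.467 for glycolysis and 0.501 for hypoxia.

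Genes of cholesterol and fatty acid synthesis and immediate early genes, which respond within minutes to receptor signals, were also lower as groups. Of 32 tested genes of lipid synthesis, 5 had a positive and 27 a negative difference. When adjusted over the list alone, 5 were lower and 1 higher, against 0 over all genes. The desaturase gene Scd1 had 8.80 ± 2.08 against 14.7 ± 2.35 TPM, Srebf2, a transcription factor of sterol synthesis, had 115.9 ± 2.71 against 125.5 ± 2.38 TPM, and Acaca, of the first step of fatty acid synthesis, was the higher one at 69.0 ± 0.745 against 63.2 ± 2.17 TPM (SD, n = 3 each). Of 28 immediate early genes, 9 had a positive and 19 a negative difference, and 7 were lower when adjusted over the list alone, against 0 over all genes. Among these 7 were Junb at 122.5 ± 3.00 against 155.5 ± 12.4 TPM and Ier2 at 72.9 ± 1.58 against 85.8 ± 5.92 TPM. Junb overlaps Prdx2 on the opposite strand. The mean log2 differences were -0.094 and -0.078, with camera adjusted p of 4.14e-07 and 0.000119. With an estimated correlation, the adjusted p was 0.656 for both lists. The mean of the immediate early list was as low in control library 1 as in the AR-deficient libraries, and the list's difference from other genes went from -0.084 to -0.053 without control library 3.

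Genes of the response to interferon gamma were higher in AR-deficient cells as a group. Of 37 tested genes, 30 had a positive difference, and 17 were higher and 1 lower when adjusted over the list alone, against 0 over all genes. The higher ones were mostly the interferon-inducible GTPases, which act against intracellular pathogens: Igtp had 234.5 ± 8.07 against 201.8 ± 1.68 TPM, Iigp1 had 34.8 ± 1.85 against 26.9 ± 1.72 TPM, and Gbp4 had 79.4 ± 6.23 against 62.2 ± 2.55 TPM (SD, n = 3 each). The signal transducer gene Stat1 was also among them. The lower one was the class II gene H2-Ab1, at 2.94 ± 0.384 against 4.51 ± 0.116 TPM. Gbp4 overlaps Gbp8 and Gbp9 on the same strand, and the Gbp genes form a family of similar sequences, so their single values are uncertain. The mean log2 difference of the list was 0.14 with a camera adjusted p of 2.09e-07, and the adjusted p with an estimated correlation was 0.656. The mean of the 3 tested B cell markers, out of 19 listed, was also higher in each AR-deficient library than in any control library. The type I interferon list had a mean log2 difference of 0.065 and a camera adjusted p of 0.118, above the threshold. Its difference from other genes, 0.060, was 0.012 without AR-deficient library 3 and 0.12 without AR-deficient library 1. It passed without AR-deficient library 1 at 9.75e-05 and without control library 2 at 0.0254, in a range over all alternatives of 9.75e-05 to 0.879.

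Genes of cytotoxic granules were lower in AR-deficient cells as a group. Of 21 tested genes, 7 had a positive and 14 a negative difference, and 8 were lower when adjusted over the list alone, against 0 over all genes. Perforin (Prf1) had 149.6 ± 1.77 against 167.8 ± 3.47 TPM, Gzmc had 81.9 ± 5.03 against 104.4 ± 11 TPM, and Srgn, a granule proteoglycan, had 518.7 ± 3.21 against 549.9 ± 6.79 TPM (SD, n = 3 each). Granzyme B (Gzmb), one of the most abundant transcripts, had 8652 ± 255 against 9480 ± 299 TPM, a difference that was 0 after quantile normalization because Gzmb has the same rank in every library. The granzymes have similar sequences, so reads shared between them could move single values. The mean log2 difference of the list was -0.10 with a camera adjusted p of 0.000433, and the adjusted p with an estimated correlation was 0.467. The mean of the 3 tested B cell markers, out of 19 listed, was higher in each AR-deficient library than in any control library. The gamma-delta T cell genes Tcrg-C2 and Trgv2 were higher when adjusted over their list alone. In that list, 7 of 11 tested genes had a positive and 4 a negative difference.

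The effector cytokines did not move one way. Ifng, which encodes interferon gamma, had 2197 ± 29.8 TPM in AR-deficient and 2322 ± 25.0 TPM in control cells, and was lower when adjusted over the list alone (adjusted p = 0.0401, limma) but not over all genes (0.153). Csf2 was lower and Ltb higher when adjusted over the list alone, at 99.8 ± 13.3 against 125.7 ± 4.11 TPM and 207.0 ± 15.3 against 166.4 ± 1.96 TPM (SD, n = 3 each). Tnf had 107.9 ± 8.22 against 91.6 ± 7.73 TPM, with a limma adjusted p of 0.215 over all genes. Il24 had 1.62 ± 0.516 against 3.37 ± 1.18 TPM, and Il2 had 8.75 ± 1.31 against 7.40 ± 0.984 TPM. The list's mean log2 difference was -0.033 and its median 0.063, so mean and median differed in sign, and its camera adjusted p was 0.770. In the list of effector transcription factors, Tbx21 had 46.9 ± 1.42 against 48.7 ± 2.43 TPM. Eomes had 71.6 ± 3.99 against 62.4 ± 1.51 TPM. Tcf7, which also stands in the list of naive and memory cells, had 81.0 ± 2.31 against 72.8 ± 3.83 TPM. Eomes and Tcf7 were higher when adjusted over the effector list of 27 tested genes alone, where 3 genes were higher and 3 lower. The camera adjusted p of that list was 0.0867. Among inhibitory receptors, Lag3 had 71.9 ± 1.03 against 86.2 ± 5.16 TPM, Pdcd1 had 48.8 ± 2.56 against 51.1 ± 0.892 TPM, Havcr2 had 27.6 ± 1.44 against 26.6 ± 0.703 TPM, and Ctla4 had 63.7 ± 17.4 against 80.9 ± 11.4 TPM. Lag3 was lower when adjusted over that list alone, where 4 of 22 genes were lower and 1 higher. The camera adjusted p of the inhibitory receptor list was 0.0627, and it ranged from 0.0154 to 0.656 over the alternatives. It passed without AR-deficient library 2 at 0.0154, without AR-deficient library 3 at 0.0282 and without control library 1 at 0.0496, and also with a minimum mean of 5 TPM (0.0262), without mitochondrially encoded and ribosomal protein genes (0.0498) and after the length and GC correction (0.0415).

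Androgen-responsive genes as a list did not differ from other genes beyond the threshold. Of 48 tested genes, 26 had a positive and 22 a negative difference, and 0 passed when adjusted over the list alone with limma. The mean log2 difference was -0.010 and the median 0.011, so the signs differed, and the camera adjusted p was 0.770. Fkbp5, a target of androgen and glucocorticoid receptors, had 109.6 ± 3.75 against 105.3 ± 2.61 TPM, Inpp4b had 114.1 ± 3.82 against 103.8 ± 1.85 TPM, and Herc3 had 15.4 ± 1.06 against 12.5 ± 0.993 TPM (SD, n = 3 each). Lower values in this list belonged to Scd1, also in the lipid synthesis list, at 8.80 ± 2.08 against 14.7 ± 2.35 TPM, and to the sterol regulator gene Insig1, at 53.05 ± 1.86 against 57.5 ± 1.40 TPM. Ptpn1, a phosphatase that acts on JAK kinases, had 102.6 ± 2.36 against 98.3 ± 4.93 TPM, with a limma adjusted p of 0.513. The list of steroid receptors and JAK-STAT regulators had a camera adjusted p of 0.770, the list of glucocorticoid-responsive genes 0.657, with a mean of -0.023 and a median of 0.018, and the p53 list 0.657. In the p53 list, 2 genes were higher and 2 lower when adjusted over the list alone, against 0 over all genes with limma. The lower ones were Cdkn1a, a cell cycle inhibitor, at 73.6 ± 3.62 against 85.1 ± 1.58 TPM, and Btg2, at 29.8 ± 0.780 against 33.2 ± 1.06 TPM. The higher ones were the death receptor gene Fas, at 19.7 ± 0.418 against 17.1 ± 0.715 TPM, and Trp53inp1, at 8.21 ± 0.702 against 6.71 ± 0.289 TPM, while Mdm2 had 62.9 ± 1.26 against 63.1 ± 0.740 TPM.

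The lists of protein folding in the endoplasmic reticulum and of mitosis were slightly higher on balance in AR-deficient cells, with members in both directions. Of 28 tested genes of the folding and heat shock list, 21 had a positive and 7 a negative difference, and 3 were higher when adjusted over the list alone, against 0 over all genes: Pdia3, Dnajc3 and Xbp1, with TPM ratios of 1.08, 1.09 and 1.09. Of 38 mitosis genes, 26 had a positive and 12 a negative difference, and Mki67 and Ect2 were higher when adjusted over the list alone, and Top2a had 341.9 ± 9.02 against 314.5 ± 10.6 TPM (SD, n = 3 each). The mean log2 differences were 0.033 and 0.034, with camera adjusted p of 0.00980 and 0.0489, and the adjusted p with an estimated correlation was 0.656 for both lists. The folding list lost its call under array weights, at 0.0713, in a range of 0.00673 to 0.656. The call of the mitosis list rests on the mean-variance trend in camera, a setting chosen after a first look at the list results, and without the trend its adjusted p was 0.0815. The mitosis list passed in 8 of 18 alternatives that kept the preset correlation. Its call was lost without AR-deficient library 1 (0.182), control library 2 (0.0665) or control library 3 (0.111) and after the length and GC correction (0.2). The range over all alternatives was 0.0104 to 0.656. The S phase list had a camera adjusted p of 0.605 and that of ribosome biogenesis 0.446.

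The lists of nuclear genes of oxidative phosphorylation and of ribosomal proteins were slightly lower on balance, and that of mitochondrially encoded transcripts was higher on balance, though no single mitochondrial gene passed. Of 75 tested nuclear genes of the respiratory chain, 25 had a positive and 50 a negative difference, and 5 were lower when adjusted over the list alone, against 0 over all genes, among them Uqcrq at 285.1 ± 8.30 against 338.3 ± 11.9 TPM and Cox8a at 456.5 ± 6.02 against 502.6 ± 3.71 TPM (SD, n = 3 each). Of 77 ribosomal protein genes, 31 had a positive and 46 a negative difference, and Rps26 and Rplp1 were lower when adjusted over the list alone, with ratios of 0.896 and 0.913, and ribosomal protein genes have many pseudogenes that can take or lend reads. The 13 mitochondrially encoded genes had a mean log2 difference of 0.36, with 12 positive and 0 past the threshold over the list alone. The mean log2 differences of the respiratory chain and ribosomal protein lists were -0.026 and -0.021. The camera adjusted p was 0.00116 for the nuclear genes, 0.00727 for ribosomal proteins and 0.00294 for mitochondrial transcripts, and the adjusted p with an estimated correlation was 0.501, 0.656 and 0.656. The share of TPM from mitochondrial transcripts was 2.60%, 2.51% and 2.27% in AR-deficient libraries and 2.64%, 1.96% and 1.37% in control libraries, so control library 1 had the highest share. Without control library 3 the mitochondrial difference from other genes went from 0.36 to 0.11, with an adjusted p of 0.119, and without control library 1 it was 0.60, in a range of adjusted p from 3.65e-10 to 0.656. The ribosomal protein difference from other genes went from -0.026 to -0.014 without AR-deficient library 1 and to -0.013 after a correction for length and GC content. Its call was lost without AR-deficient library 1 (0.172), with quantile normalization (0.0820) and after that correction (0.287), in a range of 0.000319 to 0.656. The respiratory chain difference went from -0.032 to -0.021 without AR-deficient library 1 and to -0.020 without control library 1, and its call was lost under array weights (0.0820) and after the length and GC correction (0.0556), in a range of 0.00023 to 0.501.

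**Figure D2:**
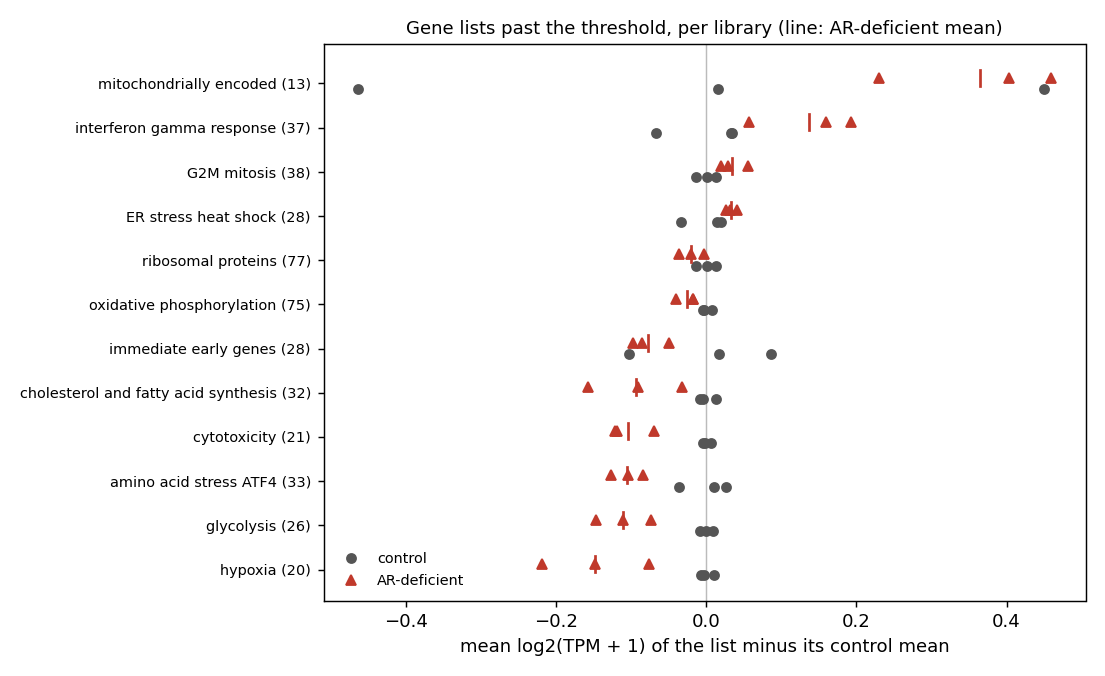
Mean log2(TPM + 1) of each of the 12 gene lists past the threshold, minus the list's mean over the control libraries (horizontal axis), per control (grey circles) and AR-deficient library (red triangles), with the number of tested genes in brackets and a line at the AR-deficient mean. The 3 AR-deficient libraries lie below all control libraries for the glycolysis, hypoxia, ATF4, lipid synthesis, cytotoxicity and oxidative phosphorylation lists. They lie above all control libraries for the interferon gamma, folding and mitosis lists. The groups overlap for the immediate early, ribosomal protein and mitochondrial lists, and the mitochondrial list spreads most among control libraries.

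Markers of other cell types gave no list past the threshold in the main test. The list of natural killer and gamma-delta T cell markers had 11 tested genes and a camera adjusted p of 0.139, and it passed with a minimum mean of 5 TPM at 0.0366, in a range over the alternatives of 0.0366 to 0.656. Of the 11 genes, 7 had a positive and 4 a negative difference. Tcrg-C2, Trgv2 and Eomes were higher when adjusted over that list alone, against 0 genes over all genes with limma. Klrc1 had lower values, at 26.0 ± 2.96 against 29.0 ± 2.13 TPM (SD, n = 3 each), with groups that overlapped. Tcrg-C2, a gamma chain constant segment, had 24.5 ± 0.652 against 20.2 ± 1.20 TPM, and Trgv2 had 12.3 ± 0.333 against 10.5 ± 0.176 TPM (SD, n = 3 each). The delta chain constant gene Trdc had 2.24 ± 0.197 against 2.09 ± 0.085 TPM. The myeloid list had 6 genes and an adjusted p of 0.372, and the list of CD4 and regulatory T cell markers 7 genes and 0.750. The list of CD8 T cell identity had an adjusted p of 0.770, and the replication-dependent histones, which show how far transcripts without a poly(A) tail were captured, had 0.298. The histone list passed without AR-deficient library 2 at 0.0295, with lower values, in a range over the alternatives of 0.0295 to 0.992. Tnfrsf4, a costimulatory receptor also found on activated CD8 T cells, had 175.1 ± 17.3 against 229.1 ± 5.22 TPM (SD, n = 3 each) and was lower when adjusted over its list alone. The B cell list had 3 tested genes of 19 and the list of erythroid, platelet and stromal markers 2 of 21, too few for the list test. Among the former, Ighm had 232.5 ± 3.17 against 213.2 ± 2.75 TPM, Cd79b had 6.81 ± 0.587 against 6.36 ± 0.265 TPM and Ighd had 1.13 ± 0.0551 against 0.987 ± 0.0503 TPM. Ighm was higher when adjusted over the list alone, against 0 genes over all genes with limma, and the mean of the 3 genes was higher in each AR-deficient library than in any control library. The apoptosis list had a camera adjusted p of 0.657, the lists of chemokines and homing 0.0833, of activation and costimulation 0.0843, and of naive and memory cells 0.481. Of the panel, Il2ra (398.0 ± 18.9 against 413.5 ± 13.3 TPM), Cd69 (97.8 ± 0.198 against 94.7 ± 5.35 TPM) and Il7r (13.7 ± 2.50 against 15.7 ± 0.545 TPM) had overlapping groups. So did Sell (77.9 ± 4.96 against 78.0 ± 3.75 TPM) and Tox (3.64 ± 0.195 against 3.81 ± 0.236 TPM). The chemokine list passed without AR-deficient library 1 at 0.00267, with no filter on low values at 0.0120, without mitochondrially encoded and ribosomal protein genes at 0.0498 and with array weights at 0.0442, in a range over the alternatives of 0.00267 to 0.656.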

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

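The length and GC correction was chosen after seeing the data. Read depth is unknown from TPM, so it could not be used to weigh genes. In 18 alternatives the list test kept its preset correlation. Over these, the ATF4, glycolysis, hypoxia, interferon gamma, lipid synthesis, immediate early and cytotoxicity lists kept their direction and stayed past the threshold. With camera at an estimated correlation 0 lists were higher and 0 lower, and 2 had an unadjusted p under 0.05. With fry 0 were higher and 0 lower. The lowest fry adjusted p was 0.0628, shared by the glycolysis and cytotoxicity lists, downward, and the natural killer and gamma-delta list, upward. The cause of the losses below was not tested, except that these tests allow for members that vary together. Of named genes, 97 results over all alternatives newly passed, 81 of them under array weights, and 0 lost a call because none had one. Array weights rested mostly on library 2 of each group, with weights of 2.58 in AR-deficient and 5.86 in control cells.

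The count of genes, 0 higher and 0 lower with limma, became 1 and 1 with a minimum mean of 5 TPM, 1 and 2 with median-of-ratios scaling, 1 and 1 with robust eBayes, 1094 and 1095 with array weights, and 47 and 61 at an adjusted p under 0.1. That count of 108 was 0 without the mean-variance trend, without a filter, with the replicate block or without AR-deficient library 3, 2 without AR-deficient library 2, 6 without control library 2, and 188 with median-of-ratios scaling, 192 with quantile normalization, 248 with robust eBayes, 253 with a minimum mean of 5 TPM and 3608 with array weights. Leaving out one library gave 0 to 11 higher and 0 to 7 lower genes. Lists higher numbered 4 and ranged from 2, without control library 3, to 5 over the libraries left out, and lists lower numbered 8 and ranged from 7 to 10. A correction for length and GC content gave 3 higher and 7 lower lists. The Ar difference kept its sign in 17 of 17 alternatives, from -0.70 to -0.13, at the smallest exact permutation p of 0.1. As a plain difference of group means, it could not change with the trend, robust eBayes, array weights or the block. Because the groups do not overlap, a pseudocount or a library left out could not turn its sign, so this count adds no support.

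The sign of some differences that were not called turned, most of them near 0. The CD8 identity list, at -0.0007 relative to other genes, was 0.0007 with a pseudocount of 5, 0.0004 without a filter, 0.0076 with quantile normalization, 0.0096 with array weights, 0.0071 after the length and GC correction, and -0.0107 to 0.0164 over libraries left out. The steroid receptor and JAK-STAT list, at -0.0055, was 0.0059 with a pseudocount of 5, 0.0147 with a minimum of 5 TPM, and -0.011 to 0.0158 over libraries left out. The S phase list, at 0.0032, was -0.0004 with a minimum of 5 TPM, -0.0009 after the length and GC correction, and -0.0027 to 0.0098 over libraries left out. The histone list, at -0.0447, was 0.0081 after that correction and -0.1119 to 0.0195 over libraries left out. The p53 list was -0.0218 to 0.0002 over libraries left out, and effector cytokines were 0.0073 with a minimum of 5 TPM. Of single genes, Sell was 0.0011 with quantile normalization, 0.0448 with array weights and -0.0552 to 0.0266 over libraries left out. Hist1h2bj was 0.0026 with array weights, 0.0568 after the length and GC correction and -0.0955 to 0.1046 over libraries left out. Lst1 was -0.0985 with array weights and -0.0188 to 0.115, and Mdm2 -0.02 to 0.0083 over libraries left out. The mitochondrial gene mt-Atp8, at 0.17 and not near 0, ranged from -0.1348, without control library 3, to 0.429.

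The groups share replicate numbers, which the labels do not tie to an animal or day. The deviations of same-numbered libraries correlated at -0.06, 0.137 and 0.009, and 2 of 6 libraries correlated best with the library of their own number. These correlations cannot exclude a shared batch, because a batch could move only some of the genes they run over. From library 1 to library 3, the mitochondrial share of TPM fell and the ribosomal protein share rose in both groups. The number of genes at a TPM of 1 or more followed no shared order. The main test did not take the numbers as pairs. With the replicate number as a block, 0 genes were higher and 0 lower (limma, 1691 at an unadjusted p under 0.05), and 5 lists were higher and 8 lower. The mitosis list did not pass with the block (adjusted p = 0.0838), and the chemokine (0.0121) and type I interferon lists (0.0344) did, at the preset correlation. Without the block, neither of these 2 passed with an estimated correlation (adjusted p = 0.656 and 0.874).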

Other observations

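The test of the state of the cultures, the tests of the Ifng and class II transcripts and both tests of the mitochondrial transcripts were chosen after the result was seen, as was the length and GC correction. The set of NRF2 targets was chosen after the single genes had been seen, but before the set was tested. The genes named in the next paragraphs were chosen after their values were seen, from lists fixed beforehand unless stated.

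Among receptors and ligands of migration, Cxcr3, a receptor for interferon-induced chemokines, had 19.6 ± 1.41 TPM in AR-deficient and 15.0 ± 0.929 TPM in control cells (SD, n = 3 each), Ccr2 had 6.27 ± 0.706 against 4.63 ± 0.361 TPM and Ccl1 had 146.6 ± 19.8 against 106.3 ± 7.65 TPM. Ccl5, at 28.1 ± 0.565 against 31.8 ± 0.571 TPM, and Ccr8, at 2.30 ± 0.338 against 3.38 ± 0.163 TPM, had lower values. With limma, these 3 higher and 2 lower genes passed when adjusted over their list of 25 tested genes alone, and 0 over all genes. Among genes of naive and memory cells, 5 were higher and 2 lower when adjusted over the list alone. Slamf6 (19.1 ± 0.823 against 16.7 ± 0.739 TPM) and S1pr1, the receptor that guides exit from lymphoid tissue (2.74 ± 0.108 against 2.12 ± 0.265 TPM), had higher values, and the chromatin organizer gene Satb1 had lower ones (188.8 ± 9.43 against 220.3 ± 1.61 TPM).

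Costimulatory and inhibitory receptors had members in both directions. With limma, 1 gene of activation and costimulation was higher and 3 lower when adjusted over the list alone, against 0 over all genes, and the higher one, Ly6a, had 450.8 ± 29.0 against 381.7 ± 2.28 TPM. Tnfrsf18 had 155.6 ± 9.64 against 186.4 ± 8.37 TPM, Cd81 had 13.01 ± 1.23 against 17.3 ± 0.330 TPM and Tigit had 157.8 ± 3.25 against 177.9 ± 3.89 TPM (SD, n = 3 each). Tnfrsf18, Cd81 and Tigit were lower with limma when adjusted over its list alone and not over all genes. The metallothionein genes Mt1 and Mt2, which encode metal-binding proteins and stand in the glucocorticoid list, had 96.1 ± 7.66 against 126.3 ± 4.19 TPM and 70.9 ± 4.22 against 86.3 ± 2.87 TPM, and were lower when adjusted over that list alone, where 4 genes were lower and 2 higher. The higher ones were the PI3 kinase inhibitor gene Pik3ip1, at 4.08 ± 0.372 against 3.13 ± 0.252 TPM, and the chemokine receptor gene Cxcr4, at 4.80 ± 0.971 against 3.34 ± 0.288 TPM.

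Nqo1 and Txnrd1, targets of the oxidative stress regulator NRF2, were among the genes with the lowest p, so a set of other NRF2 targets was fixed and tested. The 18 tested genes had a mean log2 difference of 0.055 against 0.0057 in the other genes, and 14 were positive. Srxn1 had 23.8 ± 2.01 against 18.4 ± 0.644 TPM and Gclm 59.2 ± 1.53 against 54.3 ± 0.670 TPM, while Hmox1 had 12.95 ± 0.211 against 12.8 ± 0.287 TPM (SD, n = 3 each). The set gave a camera p of 0.00834 with the preset correlation and p = 0.0462 with an estimated correlation, without adjustment for other sets. Because the set was prompted by genes of these same libraries, neither p is independent support. A slightly higher output of NRF2 targets in the AR-deficient libraries may be proposed as a hypothesis from these libraries.

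The lower glycolysis, hypoxia and ATF4 lists were weighed against technical sources. A bias from transcript length and GC content was argued against, because 91.9% of their average difference was kept after the correction, with adjusted p of at most 1.22e-06 at the preset correlation. Before the correction, the adjusted p with an estimated correlation was 0.467 for glycolysis and 0.501 for hypoxia and for the ATF4 list. A single library as the source was argued against too, since leaving out any one library left at least 82.6% of the difference. A difference in the state of the cultures for reasons other than Ar, such as cell density or oxygen, cannot be told apart from the guide RNAs. In all 3 lists the AR-deficient libraries lie below every control library, and the labels name no separate cultures. Loss of the androgen receptor stays open as the biological explanation and was not tested apart from it.

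For the higher interferon gamma response list, 99.3% of the mean difference was kept after the length and GC correction, with an adjusted p of 4.11e-09 at the preset correlation (before the correction, adjusted p = 0.656 with an estimated correlation). More Ifng transcript was argued against by the Ifng log2 difference of -0.08, although secreted protein was not measured and stays open. Antigen-presenting cells, which the CD8 enrichment would remove, stay open. The class II genes H2-Aa, H2-Ab1 and Cd74 averaged a log2 difference of -0.18, but they ranged from -0.49 for H2-Ab1 to 0.045 for Cd74 (SD of the 3 differences 0.277). Cd74, the most abundant of these 3 genes, had 21.3 ± 2.58 against 20.6 ± 1.78 TPM (SD, n = 3 each). The mean of the 3 tested B cell markers, out of 19 listed, was higher in each AR-deficient library than in any control library. The 6 tested myeloid markers, out of 30 listed, had a mean log2 difference of -0.084, with 3 positive and 3 negative (camera adjusted p = 0.372). A difference in the state of the cultures stays open too, so stronger interferon signalling in AR-deficient cells is no more than a hypothesis.

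For the higher mitochondrially encoded transcripts, a single control library may be the source. Without control library 3 the difference kept 31.9% of its size, with a camera adjusted p of 0.119. Leaving out control library 1 moved the difference from other genes the other way, from 0.36 to 0.60. Control library 3 is therefore not the only control library on which the size depends. The share of TPM from these transcripts ranged over 1.27 percentage points within the control group, against 0.468 points between the group means, so variation between libraries of one group is consistent with the pattern. The mean of the nuclear respiratory chain list had the opposite sign, at -0.026, with 25 of its 75 genes positive and 50 negative.

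Loss of the chromosome X arm beyond the cut in Ar was tested as a side effect of editing. The 151 tested genes on X beyond Ar had a mean log2 difference of 0.0142 against 0.00566 in other genes. The camera test of limma, with the preset correlation, gave p = 0.113, upward, so a lower level of these genes was not seen.

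The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes at the adjusted threshold with limma, and the highest other gave 3. All 10 splits gave as many, which a count of 0 fixes in advance, so this comparison decides nothing. At an unadjusted p under 0.05 the real split gave 1795 genes and the highest other 862, so 1 of the 10 gave as many. It gave 12 lists and the highest other 11, so again 1 of the 10 gave as many. Splits that mix the groups thus also call lists with the preset correlation. Each mixes the groups unequally, so part of the group difference stays in it. Their counts therefore cannot show how many lists would be called without a difference. The list calls still carry less weight than their adjusted p, since no list passed with an estimated correlation.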
